A study of Mus musculus with 2 samples.

How the data were processed

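The series holds 2 single-cell RNA-seq libraries of mouse tumour cells, labelled VEC and HTH, with 1 library in each group. Per the labels' protocols, tumours were dissociated with collagenase D and DNase I, passed through a 70 µm filter, and CD45-bearing cells were taken with an antibody and magnetic beads. The series text states a purity above 95% and a viability above 85% for the selected cells, and about 30000 cells loaded per sample at 1000 cells per µl. It also states 3 independent tumours per set, without saying how they were pooled. Libraries were made with droplet-based 3′ chemistry with unique molecular identifiers (UMIs), 10x Genomics version 3 per the labels, and sequenced on a NovaSeq. The barcodes look like those of an earlier version, so the chemistry is uncertain. The labels do not spell out VEC or HTH, and do not name the tumour model, dose or treatment time.

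The deposited matrices hold raw UMI counts per gene and barcode for 32285 genes, without normalisation. Per the submitters' processing notes the counts were made with Cell Ranger 5.0.1 on mm10, whereas the file headers name Cell Ranger 7.1.0. These releases differ in whether intronic reads are counted by default, and which setting was used is not given in the sources used here. Both libraries carry the same header and gene list. The VEC matrix holds 10253 barcodes and 86469545 UMIs and the HTH matrix 8505 barcodes and 87754784 UMIs. The lowest barcode totals were 501 and 500 UMIs, so barcodes below about that depth were already absent from the deposited counts. For 40 features that repeat a symbol, the identifier was appended from the repeat on.

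Barcodes with at least 200 genes and at most 15% mitochondrial UMIs were kept, which left 10190 VEC and 8433 HTH barcodes. Scrublet, the planned doublet caller, run with exact neighbours in double precision so that its scores repeat, marked 0 VEC barcodes and 1 HTH barcode at its automatic thresholds of 0.66 and 0.65, and was taken not to have worked. It was replaced, after the data had been seen, by a screen for barcodes with genes of more than 1 lineage. A barcode counted as lymphoid with at least 3 UMIs from 9 T cell genes or from 7 NK cell genes. It counted as mesenchymal with at least 10 UMIs from 9 matrix genes, as B with at least 5 UMIs from 6 genes, and as phagocyte with at least 3 UMIs and 0.2% of UMIs from 11 genes. Lymphoid barcodes were screened with 18 phagocyte and antigen presentation genes. The share and the gene sets of this screen were revised more than once, the last time because a T subcluster was still led by phagocyte genes. The screen removed 1079 VEC barcodes (10.6%) and 1260 HTH barcodes (14.9%), leaving 9111 and 7173 cells with 73974601 and 71421472 UMIs. Pairs of a phagocyte and a neutrophil, and pairs of cells of 1 lineage, are not found by this screen.

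Counts were normalised to 10000 per cell and log-transformed, 2000 variable genes were chosen within each library and combined, and 30 principal components with 15 neighbours were clustered by the Leiden method at resolution 1, without batch correction (scanpy 1.11.5, igraph 0.11.9). T-like cells were clustered again by themselves. Clusters were named from marker lists fixed in advance. A class could give a name with 3 or more markers seen in 10% of the cluster's cells, and the class with the highest mean relative marker level was taken. A cluster stayed unnamed where another class had more markers among its 10 leading genes, or where its median UMIs were more than 3 times below the median of the cells clustered and no own marker was among them. This scoring rule was written after the data had been seen. So were the joining of macrophage and monocyte markers into 1 mononuclear phagocyte class, the joining of both dendritic classes, the counting of other classes' markers against T subset names, and the total over all phagocyte clusters. That total adds unnamed clusters in which over 50% of cells passed the phagocyte rule of the barcode screen. Names are therefore "-like" names rebuilt here, and shares can differ from shares under other names. Cells with collagen and other matrix genes are called fibroblast-marker cells, because nothing in the labels gives their origin.

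Each group is 1 library, so no test, p-value or count of significant genes was made, and cells were not used as replicates. Shares of cells have exact (Clopper-Pearson) 95% binomial intervals, and the log2 ratio of the HTH to the VEC share has a log-ratio normal interval. Within each class with at least 100 cells per library, UMIs were summed per library and scaled to CPM of the class's UMIs, with exact Poisson intervals. The log2 ratio HTH over VEC has an exact conditional binomial interval. All intervals cover counting error only; they hold neither the variation between tumours nor that between cells, and are too narrow where a few cells carry most UMIs of a gene. A ratio with 0 UMIs in 1 library is given as the exact limit of its interval, and a level of 0 UMIs as a bound from 3 counts.

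Genes named in the text follow a rule fixed in advance. It takes genes with at least 50 UMIs over both libraries and at least 50 CPM in one, without mitochondrial, ribosomal protein, haemoglobin and antigen receptor segment genes. Genes more than 10 times below their highest class level in both libraries were left out. They were ranked by the interval bound nearest 0, with a minimum of 1.5-fold, taking 12 each way in the 4 largest classes and 5 each way in other classes. Up to 4 members of each described list were added, and genes the series title calls for, of which Nuak1 and Hmgcs1 are given. Some genes that the rule takes are not reported here. Genes printed from outside this rule are said to be so.

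Gene lists, like the markers, the rule for named genes and most of the other settings tried, were fixed before the data were examined (30 lists, 586 genes; 10 list or marker symbols have no entry in the matrix). A list's value is the median log2 ratio of its members with at least 20 UMIs, with 0.5 added to each sum. Its interval comes from 1000 Poisson draws, and its percentile from 10000 random lists of equal size drawn from the 100 genes nearest to each member in mean CPM. This percentile describes these 2 libraries and is no test. In the compared classes 112 list medians were computed, and the 44 described were chosen after the values were seen. They are those outside the middle 95% of random lists with at least 3 members beyond 1.5-fold or a median of at least 0.2 in size, and the mevalonate and NUAK lists everywhere. The other 68 medians lay between -0.19 and 0.20 and were not carried through the alternatives, so fewer reversed medians are counted than all lists would give. Which lists count as leading results was also chosen after the medians were seen. For fibroblast-marker cells, the lists beyond those planned for every class were added after seeing the data.

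Genes detected per cell were compared after thinning every cell to 1000 UMIs. Intervals of gene ratios and the recovery of list medians were tried on simulated Poisson counts, drawn for 12112 genes from the phagocyte sums, with 200 genes altered. These counts follow the model behind the intervals and hold no spread between cells, so coverage near the nominal level was built in. Of unaltered genes 95.7%, and of altered genes 92.5%, had an interval holding the true value, and 100% of the 2-fold and 100% of the 1.5-fold genes had an interval on the right side of 0. A list set to -0.5 was recovered at -0.50. Intervals of list medians, shares, clustering, the barcode screen, thinning and matching had no such test. Gene coordinates are from the GENCODE annotation of the same build, mm10, which may differ in detail from the annotation used for counting. Counts of near-identical genes, such as Hspa1a and Hspa1b, Ifit3 and Ifit3b, or members of the granzyme, Klra and cystatin A families, can be split between copies and are less certain.

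Alternatives were other cell filters, doublets kept, other clustering settings, other scalings of the sums, higher list minimums and other thinning depths. Alternatives added after seeing the data were Scrublet scores ranked, looser and stricter barcode screens, a total without fibroblast-marker cells, matching on stress genes, neutrophils without phagocyte genes, and sums without the single cell holding most UMIs of a gene. Matching on stress shrinks differences in genes of the stress list itself, such as Hspa1a and Hspa1b, by construction. For such genes the matched ratio is no check, in any class. Explanations in the closing section were weighed against bounds. That a counting interval must clear its bound was required only after the values were seen, and altered no outcome. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.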

Results

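Immune cells selected on CD45 from mouse tumours were profiled by single-cell RNA-seq in 2 libraries, VEC and HTH, with 1 library per group. The series title concerns inhibition of the kinase NUAK1, blocking of the mevalonate pathway, which makes cholesterol and isoprenoids, and immunity against tumours. The comparison between the libraries therefore asks how the makeup and gene expression of tumour immune cells differ between the groups. The VEC library held 9111 kept cells with a median of 5738 UMIs and 1711 genes, and the HTH library 7173 kept cells with a median of 6764 UMIs and 1868 genes. With no replicate library, every difference below is a difference between these 2 libraries, has no replicate check, and is given with counting error only.

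Clusters of phagocytes held most cells in both libraries and took a lower share in HTH. Named mononuclear phagocyte-like clusters and 3 unnamed clusters, in which most cells carried phagocyte genes, together held 71.7% of VEC cells (95% exact binomial interval 70.8 to 72.6%) and 62.2% of HTH cells (61.1 to 63.4%), a log2 ratio of -0.20 (-0.24 to -0.17). T-like cells, which carry the T cell receptor complex, were 5.61% of VEC cells (5.14 to 6.10%) and 8.73% of HTH cells (8.08 to 9.40%), with a log2 ratio of 0.64 (0.48 to 0.80); the shares were 12.5% and 19.3% with doublets kept, and 11.2% and 17.9% with Scrublet scores ranked. NK-like cells were 2.57% and 3.18% (log2 ratio 0.31, 0.05 to 0.57). Cells with collagen and other matrix genes, which a CD45 selection should remove, were 1093 of the 9111 VEC cells (11.3 to 12.7%) and 1263 of the 7173 HTH cells (16.7 to 18.5%), with a log2 ratio of 0.55 (0.45 to 0.66). For dendritic-like cells (3.37% and 3.74%, log2 ratio 0.15) and neutrophil-like cells (4.62% and 4.08%, log2 ratio -0.18) the interval of the ratio included 0. The neutrophil-like log2 ratio was -0.23 (-0.44 to -0.03) with doublets kept and -0.22 (-0.42 to -0.02) at a phagocyte share of 0.4% in the barcode screen. The dendritic-like one was 0.24 (0.01 to 0.48) without fibroblast-marker cells in the total, but -0.14 at resolution 2.

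The shares depend on one another and on the bead selection. Without fibroblast-marker cells in the total, the phagocyte log2 ratio was -0.11 and the T-like one 0.73. Named mononuclear phagocyte-like clusters alone held 57.0% and 47.6% of cells. Clusters left unnamed held 14.8% of VEC and 15.1% of HTH cells. The first, led by MHC class II genes with Ccr2 and Itgax, and with more dendritic than phagocyte markers among its leading genes, held 6.97% and 8.53%, a shallow one led by Retnla and Lpl 4.31% and 3.76%, and one led by Saa3, Il1a and Nos2 3.40% and 2.38%. The last unnamed cluster, led by immunoglobulin genes, had 11 VEC and 30 HTH cells. With each library clustered alone, the log2 ratio was -0.41 for NK-like, -1.79 for dendritic-like and -0.07 for named mononuclear phagocyte-like cells, so the NK-like difference depends on joint clustering. The interval of the NK-like log2 ratio also included 0 at 500 genes (0.21, -0.04 to 0.46), with doublets kept (0.19, -0.03 to 0.40) and with Scrublet scores ranked (0.17, -0.06 to 0.40).

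**Figure D1:**
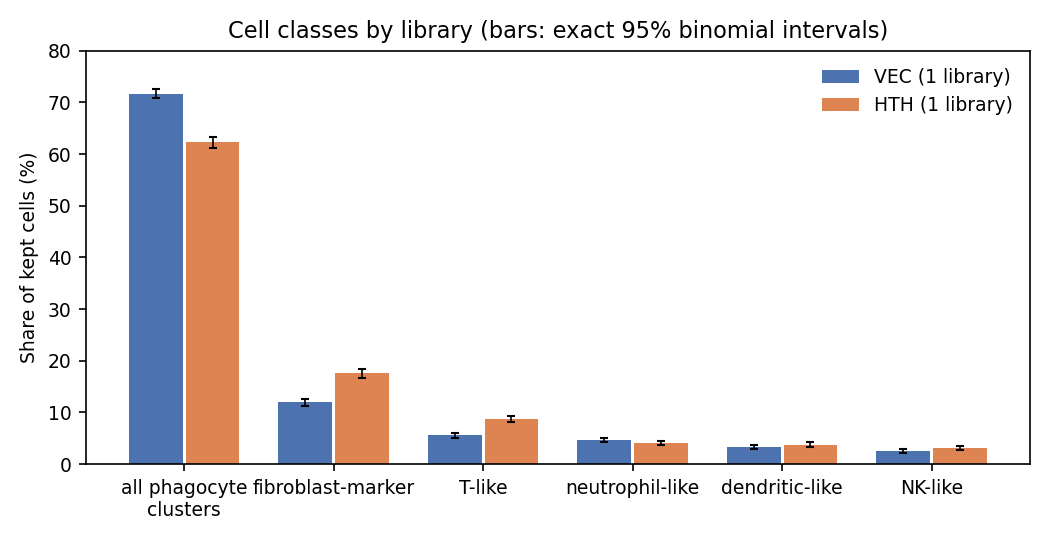
Share of kept cells (%, y axis) in 6 classes (x axis) for the VEC and HTH libraries, 1 library each, with exact 95% binomial intervals as error bars. The phagocyte share is 71.7% in VEC and 62.2% in HTH, and the T-like share 5.61% and 8.73%.

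Among T-like cells, CD8 T-like cells, the cytotoxic lineage, were the largest subset, with 52.1% of 511 VEC and 57.3% of 626 HTH cells (log2 ratio 0.14, -0.01 to 0.29). Regulatory T-like cells, which carry Foxp3 and restrain immune responses, were 8.41% (43 cells) and 6.07% (38 cells), with an interval of the log2 ratio from -1.08 to 0.14. That log2 ratio was -0.63 (-0.99 to -0.28) with doublets kept, -0.45 (-0.81 to -0.09) with Scrublet scores ranked and -0.91 (-1.65 to -0.17) at a phagocyte share of 0.1% in the barcode screen. Gamma delta or innate-like T cells, led by Il17a and Trdc, were 4.50% (23 cells) and 2.24% (14 cells), with a log2 ratio of -1.01 (-1.95 to -0.07). That log2 ratio was -0.86 (-1.79 to 0.07) at a phagocyte share of 0.1%, and the direction of the counts turned with each library clustered alone. Other CD4 T-like cells were 9.20% and 8.31%, naive-like T cells 4.70% and 5.27%, and unnamed T clusters 21.1% and 20.8%. In 1 of the unnamed T clusters, with 5.28% of VEC and 5.59% of HTH T-like cells, the phagocyte genes Wfdc17, Pf4 and Arg1 led. Subset names moved with the clustering. The CD8 log2 ratio was 0.48 (0.28 to 0.68) at 10% and 0.36 at 25% mitochondrial UMIs, 0.59 (0.38 to 0.80) without state lists, 0.32 with doublets kept and 0.51 at a phagocyte share of 0.1%, but -1.61 with each library clustered alone, and the VEC share ran from 21.2% to 63.5%.

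Nuak1, the kinase gene in the series title (ENSMUSG00000020032, mm10 chromosome 10, 84370905 to 84440597, protein coding), was near the detection limit in these cells. It had 120 UMIs among all kept VEC cells (1.62 CPM) and 133 among HTH cells (1.86 CPM), a log2 ratio of 0.20 (-0.17 to 0.57). Most of these UMIs were in fibroblast-marker cells, with 84 (3.25 CPM) in VEC and 94 (2.88 CPM) in HTH. Hmgcs1, an early enzyme of the mevalonate pathway (ENSMUSG00000093930, chromosome 13, 119690379 to 119708260), stood at 94.6 and 108 CPM over all cells (log2 ratio 0.19, 0.15 to 0.24). Within classes Hmgcs1 stood at 191 and 180 CPM in fibroblast-marker cells (-0.086, -0.14 to -0.031) and at 34.2 and 33.0 CPM in mononuclear phagocyte-like cells (-0.053, -0.19 to 0.080). Fibroblast-marker cells held 25851653 of the 73974601 VEC UMIs and 32628840 of the 71421472 HTH UMIs. The ratios of Nuak1 and Hmgcs1 over all cells therefore also hold this difference in makeup. An inhibitor of the NUAK1 protein need not alter the mRNA, so these levels check no label.

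Medians of mevalonate and cholesterol synthesis genes lay between -0.30 and 0.20 in the 6 classes. The median was -0.09 (-0.15 to -0.04) in mononuclear phagocyte-like cells, with 0 of 26 measured members beyond 1.5-fold, -0.06 in fibroblast-marker cells and -0.04 in dendritic-like cells. In fibroblast-marker cells the median was 0.00 when scaled by the median of gene ratios, and 2 of 26 members were lower, with Scap, a regulator of sterol synthesis (8.86 and 5.79 CPM), as an example. In T-like cells the median was 0.19 (0.02 to 0.31) at percentile 99.7, but 0.023 with doublets kept and 0.033 as a mean of per-cell CPM. There Fdft1, squalene synthase, stood at 28.5 and 46.6 CPM, Mvk, mevalonate kinase, at 6.85 and 12.3 CPM and Hmgcs1 at 59.0 and 87.2 CPM. In CD8 T-like cells it was 0.17 with 7 of 25 members higher and 2 lower, Fdft1 among the higher, but -0.01 with doublets kept. The NK-like median was 0.20 (-0.02 to 0.34), with Hmgcs1 at 51.8 and 79.9 CPM. In neutrophil-like cells the median over 12 members was -0.30 with an interval from -0.59 to 0.21, and the 1 dendritic-like member beyond 1.5-fold was Ggps1, at 12.5 and 20.1 CPM.

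The list of NUAK kinases and associated genes had medians of 0.05 in mononuclear phagocyte-like, 0.08 in NK-like, -0.05 in dendritic-like, -0.13 in fibroblast-marker and -0.16 in neutrophil-like cells, over 6 to 8 measured members. In T-like cells it was -0.29 (-0.53 to -0.06), with Mark2, a kinase of the same family, at 75.4 and 44.9 CPM and Myc, the growth-promoting transcription factor, at 27.4 and 43.0 CPM, opposite in direction. In CD8 T-like cells it was -0.22 (-0.53 to 0.02), and in neutrophil-like cells Stk11, an upstream kinase, stood at 67.8 and 38.0 CPM.

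In mononuclear phagocyte-like cells, several genes of alternative activation were lower and several inflammatory genes higher in HTH. Retnla, which interleukin-4 type signals induce (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461), was 13.3-fold lower, at 143 CPM (95% exact Poisson interval 139 to 147) in VEC and 10.8 CPM (9.47 to 12.2) in HTH. The chemokine Ccl24 was 4.15-fold lower (282 and 68.0 CPM), Ccl8 (ENSMUSG00000009185, chromosome 11, 82115185 to 82116799) 3.65-fold lower (1833 and 502 CPM) and Chil3, a chitinase-like protein, 3.37-fold lower (394 and 117 CPM). Hspa1b, an inducible heat shock protein (ENSMUSG00000090877, chromosome 17, 34956436 to 34959238), was 2.70-fold higher, at 66.1 CPM (63.3 to 68.9) and 179 CPM (173 to 184). Tnf, a central inflammatory cytokine, was 1.89-fold higher (43.6 and 82.2 CPM), Ptgs2, the inducible cyclooxygenase, 1.87-fold higher (208 and 388 CPM), and Cxcl10, which attracts activated T cells, 1.60-fold higher (249 and 400 CPM). These sums rest on 5196 VEC and 3412 HTH cells with 32928247 and 23421320 UMIs, and leave out the unnamed phagocyte clusters. Of the cells in all phagocyte clusters, the unnamed one led by Retnla and Lpl held 6.01% in VEC and 6.05% in HTH. The unnamed one led by Saa3, Il1a and Nos2 held 4.74% and 3.83%. The one led by MHC class II genes, with Ccl24 among its leading genes, held 9.72% and 13.7%.

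The other higher genes were Hspa1a, near-identical to Hspa1b (log2 ratio 1.18), the monocyte gene Plac8 (1.04), the NF-κB pathway genes Nfkbiz (0.82), Nfkbia (0.74) and Traf1 (0.79), Zfp36, which speeds the decay of cytokine mRNA (0.71), the immediate early gene Jun (0.69) and the cytokine Il1a (0.70). Matched on the share of UMIs in stress genes, log2 ratios were 0.64 for Hspa1b, 0.43 for Hspa1a, 0.56 for Plac8, 0.50 for Tnf, 0.27 for Zfp36 and 0.12 for Jun. Genes of the stress list itself, such as Hspa1a and Hspa1b, fall by construction of the matching. The other lower genes were Mfge8, which bridges dying cells to phagocytes (-1.37), Wfdc17 (-1.30), the lysosomal glycoprotein Gpnmb (-1.24), the coagulation factor F7 (-1.19), the growth factor Hbegf (-1.05), the lectin Mgl2 (-1.03), the collagenase Mmp13 (-0.85) and the lysosomal protease Ctsd (-0.80). Retnla UMIs came from 131 VEC and 23 HTH cells, and 1 VEC cell held 19.6% of them. Ccl8, Chil3, Gpnmb, Ctsd and Plac8 are also class markers, and several of these genes lead single phagocyte clusters. Of the cells in phagocyte clusters, the cluster led by Mmp13 and Gpnmb held 19.7% in VEC and 13.3% in HTH, that led by Ly6i and Plac8 11.8% and 16.5%, and one led by Ace, with Plac8 among its leading genes, 1.84% and 4.12%. That led by Areg and Ccl24 held 18.9% and 16.5%, that led by Ccl12 and Ccl8 17.5% and 15.7%, and a named one led by Retnla 1.30% (85 cells) and 0.515% (23 cells), a log2 ratio of -1.34 (-2.00 to -0.67).

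**Figure D2:**
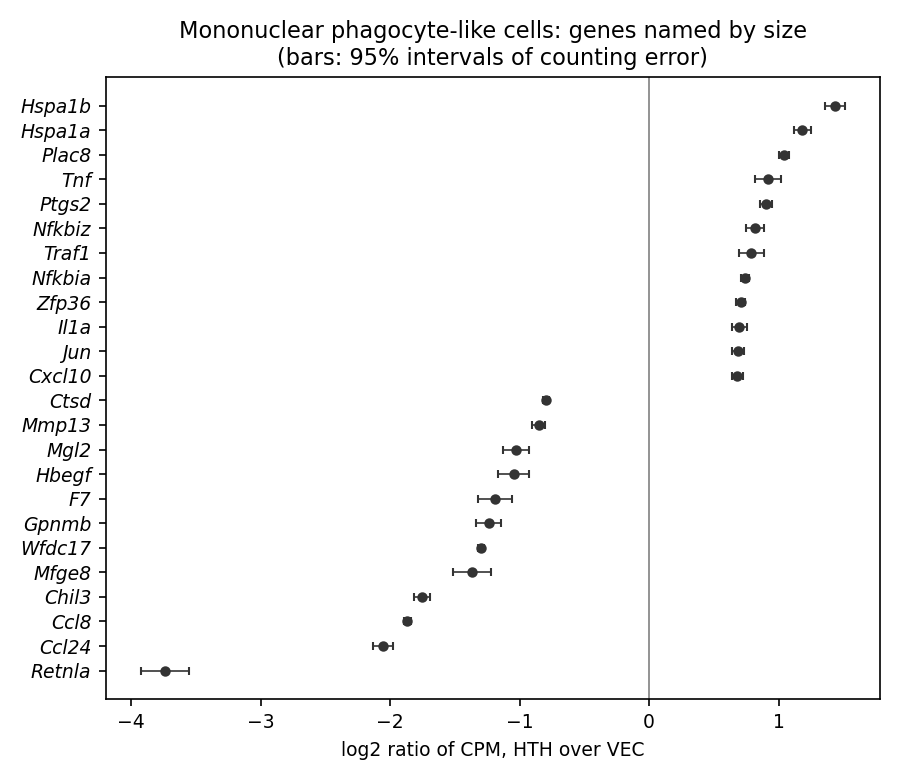
Log2 ratio of CPM, HTH over VEC (x axis), of the 24 genes named by size in mononuclear phagocyte-like cells (y axis), summed over 1 library per group, with 95% intervals of counting error. Values run from -3.73 for Retnla to 1.43 for Hspa1b.

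By list, 11 of 24 alternatively activated macrophage genes were lower by at least 1.5-fold and 0 higher, with a median log2 ratio of -0.49 (-0.59 to -0.42) at percentile 0 of the random lists. Of 23 measured pro-inflammatory genes, 8 were higher and 0 lower, with a median of 0.36 (0.27 to 0.40) at percentile 100; Il23a, a subunit of interleukin-23, stood at 0.97 and 3.89 CPM. Of 24 dissociation stress genes, which respond to enzymatic digestion, 5 were higher and 0 lower, with a median of 0.37 (0.34 to 0.42). Matched on the share of UMIs in those stress genes, the pro-inflammatory median was 0.18. Lipid-associated macrophage genes had a median of -0.17 (-0.25 to -0.16), with 3 of 20 lower, among them Gpnmb and Ctsd. Of 20 chemokine genes, 2 were higher, with Cxcl10 as an example, and 4 lower, with Ccl24 and Ccl8 as examples (median -0.14), and the G2 and M phase median was 0.21 (0.17 to 0.27) with 0 of 28 members beyond 1.5-fold, beside a cycling phagocyte cluster with 5.83% and 7.70% of the cells in phagocyte clusters (log2 ratio 0.40, 0.20 to 0.60). The interferon-stimulated median was 0.00 and that of MHC class II antigen presentation 0.15, and all 14 lists outside the rule for description, both of these included, lay between -0.13 and 0.17.

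In dendritic-like cells (307 VEC and 268 HTH), Plac8 and the immediate early gene Jun were higher in HTH. Plac8 stood at 233 CPM (215 to 252) and 494 CPM (466 to 523), and Jun at 269 and 515 CPM. Cd7, a surface protein (log2 ratio 1.58), Dusp2, a phosphatase of stress kinases (1.28), and the transcription factor Klf2 (1.08) were also higher. Matched on stress, log2 ratios were 0.54 for Jun and 0.63 for Klf2. Lower were the growth factor Areg (-1.34), Ccl8 (-1.18), the small GTPase Rhoc (-1.17), Ctsd (-1.05) and the macrophage elastase Mmp12 (-1.02). Ccl8, Ctsd and Mmp12 are also phagocyte genes, and RNA from phagocytes in these cells was not excluded. In HTH, 1 cell held 95.3% of the Ccl8 UMIs, and the log2 ratio without the top cell of each library was -4.89.

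Dendritic cell activation genes had a median of -0.18 (-0.23 to -0.08), with 3 of 26 lower and 1 higher. The cluster led by Ccr7, Ccl22 and Fscn1, genes of activated dendritic cells, held 98 of 307 VEC and 70 of 268 HTH cells of the class. The larger cluster, with Plet1, Ccl17 and Cd209a among its leading genes, held 209 and 198 cells. Batf3, a transcription factor of cross-presenting dendritic cells, stood at 93.5 and 55.8 CPM, but neither cluster had Xcr1 or Clec9a, markers of such cells, among its leading genes. Il15, a cytokine that sustains T and NK cells, was at 24.6 and 15.1 CPM. Tnfsf9, a costimulatory ligand, was higher, at 72.7 and 136 CPM. The interferon-stimulated median was 0.13 (0.08 to 0.23) with 3 of 34 higher, Ifit3 at 16.3 and 24.8 CPM (log2 ratio 0.14 matched on stress). The S phase median was 0.25 with 4 of 24 higher and 2 lower, Fen1 (20.5 and 36.1 CPM) and Rrm1 (26.9 and 16.4 CPM) as examples. Dissociation stress genes had a median of 0.28 (0.23 to 0.35), with 4 of 24 higher, and Hspb1, a small heat shock protein, at 3.03 and 21.0 CPM, from 2 VEC and 9 HTH cells. The 10 other lists lay between -0.12 and 0.12.

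In neutrophil-like cells (421 VEC and 293 HTH), G0s2 and Cxcl2 were higher and the phagocyte genes Ccl8, Chil3 and Gpnmb lower in HTH. G0s2, an inhibitor of fat breakdown, stood at 1430 CPM (1352 to 1512) and 3398 CPM (3256 to 3545), and Cxcl2, which attracts neutrophils, at 12590 and 22468 CPM. Higher too were Cxcl1 (log2 ratio 1.62), tissue factor F3 (1.56), Hspa1b (1.53), Dusp2 (41.4 and 117 CPM), Hspa1a (1.28), Csta2 (1.15), Socs3, which restrains cytokine signals (1.11), the MHC class II gene H2-Eb1 (1.10), Zfp36 (1.08) and Ptgs2 (1.02). Cxcl1 had UMIs in 16 VEC and 18 HTH cells, Hspa1b in 17 and 19, Csta2 in 40 and 23 and H2-Eb1 in 62 and 47. The top HTH cell held 28.2% of the Cxcl1, 24.3% of the Hspa1b, 28.2% of the Csta2 and 14.9% of the H2-Eb1 UMIs. Without the top cell of each library, these 4 log2 ratios were 1.43, 1.47, 0.84 and 1.04. Matched on stress, log2 ratios were 0.76 for G0s2, 0.43 for Cxcl2, 0.97 for F3, 0.89 for Hspa1a, 0.68 for Socs3, 0.39 for Zfp36 and 0.59 for Ptgs2. Lower were the chemokines Ccl8 (-3.28), Ccl12 (-2.78), Ccl2 (-1.66) and Pf4 (-1.59), and Cstdc5 (-3.19), Chil3 (-2.89), Gpnmb (-2.83), Mmp13 (-2.54) and the fatty acid binding protein Fabp5 (-1.67). Ccl8 had UMIs in 46 VEC and 7 HTH cells, Chil3 in 26 and 9 and Gpnmb in 22 and 2, and pairs of a phagocyte and a neutrophil are not found by the barcode screen. The granule genes Ngp, Camp and Ltf were ranked as lower, but 1 VEC cell held all 407 Ngp UMIs, 1 held 232 of 234 Camp UMIs and 1 held 123 of 127 Ltf UMIs. Without the top cell of each library the log2 ratio was 0.46 for Ngp, 0.99 for Ltf and -1.86 for Camp, each on few UMIs.

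The chemokine list in neutrophil-like cells had a median of -0.42 (-0.52 to -0.32), with 8 of 17 lower and 4 higher, but -0.11 without cells carrying phagocyte genes. Without those cells the Hspa1a log2 ratio was -1.12, against 1.28 with them. Of the other gene values in this class, 10 moved beyond counting error without those cells and 14 stayed within it. The interferon-stimulated median was 0.11 (0.02 to 0.31), with 5 of 35 higher and 2 lower, Ifi47 at 313 and 517 CPM, Herc6 at 29.9 and 66.6 CPM, Ifit3 at 72.4 and 41.2 CPM and Ifit3b at 50.6 and 28.5 CPM. It was -0.01 as a mean of per-cell CPM. Of 23 stress genes, 8 were higher and 1 lower, with a median of 0.36 (0.21 to 0.46). The 8 other lists lay between -0.17 and 0.13.

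In T-like cells (511 VEC and 626 HTH), the medians of cell cycle genes were above 0, while those of cytotoxic and exhaustion genes were close to 0. The median of S phase genes was 0.31 (0.26 to 0.43), with 4 of 26 higher and 0 lower, Cdc45 (9.89 and 24.7 CPM) and Gins2 (19.8 and 36.5 CPM), both of DNA replication, as examples. For G2 and M phase genes it was 0.30 (0.24 to 0.41), with 4 of 28 higher and 0 lower, among them Cdc20 (25.1 and 43.2 CPM) and Cdk1 (57.5 and 87.9 CPM), which drive mitosis. A T cluster led by the cell cycle genes Birc5, Ube2c and Stmn1 held 13.7% of VEC and 19.2% of HTH T-like cells (log2 ratio 0.48, 0.09 to 0.88). The cytotoxic effector median was 0.04 (-0.04 to 0.08) and that of inhibitory receptors and exhaustion -0.04 (-0.11 to 0.11). The interferon gamma response median was -0.23 (-0.32 to -0.08), with 2 of 22 lower, Iigp1 (12.2 and 6.01 CPM) and Gbp2 (42.2 and 27.9 CPM), and 1 higher. Dissociation stress genes had a median of 0.28 (0.24 to 0.39), with 7 of 24 higher, Hspb1 at 5.71 and 20.9 CPM from 8 VEC and 21 HTH cells, and 1 lower, Klf4, at 16.7 and 10.6 CPM.

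Of the CD4 helper cytokine and regulator list, 6 of 12 measured genes were higher and 1 lower, with a median of 0.57 (0.29 to 0.83), but 0.04 with doublets kept and 0.28 matched on stress. Il13, a type 2 cytokine, stood at 24.7 and 113 CPM, but 398 of its 469 HTH UMIs came from 1 cell. Il2, the T cell growth factor, had 0 UMIs in VEC and 192 in HTH, a log2 ratio with an exact lower limit of 5.02, and 1 cell held 158 of them. Cd40lg, a helper ligand, stood at 17.5 and 11.1 CPM.

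Genes ranked as higher in T-like cells were Gm156 (log2 ratio 1.46), Spp1 (1.11), Hspa1a (1.03), Gm43305 (0.97), the NK-type receptor Klra5 (0.96), the inositol synthase Isyna1 (0.95), Jun (0.94), Tnf (0.90), the granzyme Gzmg (0.84), Hspa1b (0.76) and Klf2 (0.74), besides Il13. Matched on stress, log2 ratios were 0.51 for Jun, 0.47 for Hspa1a, 0.34 for Klf2 and 0.22 for Hspa1b. A T cluster had Hspb1, the T cell receptor segment Trav21-dv12, Gm156 and Klra5 among its leading genes. That cluster held 22 VEC cells (4.31% of T-like cells) and 66 HTH cells (10.5%), a log2 ratio of 1.29 (0.62 to 1.97). Whether it holds a clone was not tested. A single cell held 58.2% of the Gzmg UMIs in VEC and 52.6% in HTH, and Spp1, a phagocyte gene too, had a log2 ratio of -0.04 with doublets kept. Lower were the insulin signalling adaptor Irs2 (52.5 and 26.2 CPM), Rnf19b (-0.95), Tecpr1 (-0.89), the chemokine receptor Cxcr4 (-0.86), the protease Adam8 (-0.84), Lars2 (-0.78), cyclin D2, Ccnd2 (-0.77), Sv2c (-0.75), Mark2 (-0.75), Ly6a (-0.64), Ccl1 (-0.64) and the integrin Itgal (-0.63). Lars2 was also a leading gene of a T cluster of low depth (median 1696 UMIs), named CD8 T-like, with 31 VEC cells (6.07%) and 18 HTH cells (2.88%), a log2 ratio of -1.08 (-1.90 to -0.26). The 10 lists outside the rule for description, the cytotoxic and exhaustion lists included, lay between -0.08 and 0.09.

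Within the CD8 T-like subset (266 and 359 cells), Gm156 (log2 ratio 1.39), Isyna1 (1.41), Fos (1.13), Jun (1.07) and Hspa1a (0.94) were higher, with 0.79, 0.64 and 0.38 for Fos, Jun and Hspa1a matched on stress. Lars2 (-0.81), Gm42418 (-0.67), Kbtbd11 (-1.14), the corepressor Tle3 (-1.07) and Tecpr1 (-1.02) were lower. Gm42418 is a locus whose counts are known to include ribosomal RNA, and stood at 39668 CPM in VEC and 24903 CPM in HTH. The cluster of low depth led by Gm26917 and Lars2 was 31 of the 266 VEC and 18 of the 359 HTH cells of this subset. The S phase median was 0.27 with 3 of 26 higher, and the stress median 0.32 with 8 of 24 higher. The 11 other lists lay between -0.14 and 0.20.

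In NK-like cells (234 VEC and 228 HTH), Ifng and Myc were higher and many cell cycle genes lower in HTH. Ifng, the interferon that activates macrophages, stood at 34.0 CPM (26.4 to 43.2) and 93.5 CPM (79.8 to 109), Myc at 29.0 and 87.9 CPM, and Pdcd1, an inhibitory receptor, at 76.7 CPM (65.0 to 90.0) and 10.8 CPM (6.49 to 16.8). Pdcd1 UMIs came from 30 VEC and 7 HTH cells, and the log2 ratio without the top cell of each library was -2.88. Pdcd1 is also a leading gene of a T-like cluster, and T cells under the NK-like name were not excluded. The cytotoxic effector median was 0.27 (0.20 to 0.36), with 5 of 19 higher, Ifng and the chemokine Ccl3 (37.6 and 99.8 CPM) among them, and 0.14 matched on stress. The log2 ratio was 1.46 for Ifng and 1.41 for Ccl3, but 0.51 and 0.61 matched on stress, and Myc went from 1.60 to 0.99. Of 27 G2 and M phase genes 16 were lower, with a median of -0.63 (-0.81 to -0.42), Mki67 at 82.3 and 36.3 CPM and Top2a at 98.5 and 55.6 CPM. Of 24 S phase genes 10 were lower (median -0.54), with Rrm2 at 56.9 and 22.7 CPM and Dut at 201 and 118 CPM.

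Jun (log2 ratio 1.16), Hspa1a (1.22) and the chaperone partner Dnajb1 (1.22) were also higher in NK-like cells. They stood at 0.37, -0.018 and 0.22 matched on stress, where genes of the stress list itself, such as Hspa1a, fall by construction. The stress median was 0.44 (0.33 to 0.52), with 8 of 24 higher, Hspb1 at 4.57 and 31.2 CPM from 2 VEC and 7 HTH cells, and 1 lower, Egr1, at 61.0 and 39.1 CPM. Lower were Ccl8 (-2.63), Wfdc17 (-2.28), Mmp13 (-2.22) and the tetraspanin Cd63 (-1.96), which are abundant in phagocytes. The interferon-stimulated median was -0.35 with 8 of 27 lower, Ifi27l2a at 131 and 61.2 CPM and Isg15 at 88.9 and 57.8 CPM, but 0.13 with at most 10% mitochondrial UMIs. The STING and type I interferon induction median was -0.44 with 4 of 9 lower, Ddx41 at 40.1 and 22.7 CPM and Irf7 at 35.6 and 23.2 CPM, but 0.19 at that limit. There fewer cells took the NK-like name, 159 VEC and 187 HTH, so these medians depend on class membership. The 5 other lists lay between -0.19 and 0.04.

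In fibroblast-marker cells (1093 VEC and 1263 HTH), several interferon-induced genes were lower in HTH. Ifit3 stood at 59.9 CPM (56.9 to 62.9) and 30.2 CPM (28.4 to 32.2), Isg15, a ubiquitin-like modifier, at 282 and 183 CPM, and Rsad2, which blocks viruses, at 28.7 and 12.9 CPM. Of 36 interferon-stimulated genes 8 were lower and 0 higher, with a median of -0.33 (-0.38 to -0.25) at percentile 0. Of 27 interferon gamma response genes 4 were lower (median -0.21), with the tryptophan-degrading Ido1 at 29.2 and 17.6 CPM and Nos2, the inducible nitric oxide synthase, at 7.19 and 4.47 CPM. Of 14 checkpoint and immunoregulatory genes 2 were lower (median -0.22), Ido1 and Arg1, arginase, at 31.5 and 16.6 CPM. Arg1 is also a leading gene of a phagocyte cluster. The phagocyte chemokines Ccl8 (63.3 and 32.1 CPM) and Ccl24 (1.97 and 0.521 CPM), both from outside the rule for named genes, were lower in these cells too. Slurp1 (log2 ratio -0.89), Mid1 (-0.64) and Ptgs2 (-0.64) were also lower. Fos, an immediate early gene, was the 1 gene ranked as higher, at 324 and 502 CPM (log2 ratio 0.63, and 0.34 matched on stress), and Hspb1 stood at 2.36 and 12.4 CPM, with UMIs in 5 VEC and 11 HTH cells, of which 1 cell held 78.7% in VEC and 53.2% in HTH. The stress median was 0.13 (0.11 to 0.16) with 3 of 24 higher, and the median log2 ratio over all measured genes was -0.06. The 10 other lists lay between -0.13 and -0.02. The smaller cluster of this class, with 522 VEC and 609 HTH cells, was led by Tubb3, Anln and cell cycle genes such as Ube2c, Cdc20 and Birc5. In that cluster 16 fibroblast markers were detected, but 0 were among its 10 leading genes.

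**Figure D3:**
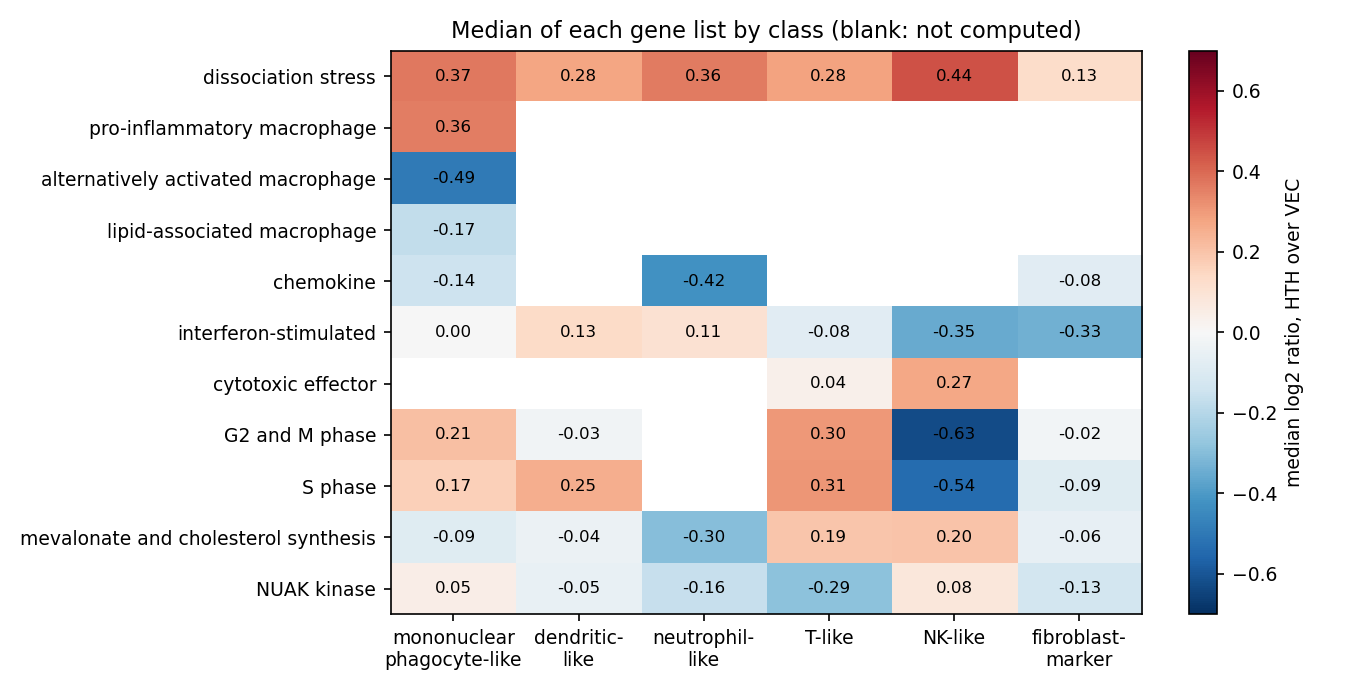
Median log2 ratio, HTH over VEC, of 11 gene lists (y axis) in 6 cell classes (x axis), 1 library per group, with the value printed in each cell. The stress list is above 0 in all 6 classes, from 0.13 to 0.44, and the alternatively activated list is at -0.49 in mononuclear phagocyte-like cells.

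Genes detected per cell, at 1000 UMIs for every cell, were 527 in both libraries in mononuclear phagocyte-like cells, 549 and 551 in T-like, 524 and 525 in NK-like and 538 and 541 in dendritic-like cells. Fibroblast-marker cells had 604.5 and 594 genes, and CD8 T-like cells 543.5 and 552. Neutrophil-like cells had 494 and 448 genes, but 195 of 421 VEC and 94 of 293 HTH cells were too shallow to enter. Cells left out as too shallow were 72 and 37 phagocyte-like, 15 and 19 T-like, 10 and 5 NK-like, 0 and 1 dendritic-like, 13 and 16 fibroblast-marker and 10 and 13 CD8 T-like cells. Without thinning, the medians were 1642 and 1712 in phagocyte-like, 1473 and 1706 in T-like, 1963.5 and 1603.5 in NK-like, 2142 and 2149 in dendritic-like, 4555 and 4711 in fibroblast-marker, 1548.5 and 1921 in CD8 T-like and 470 and 478 in neutrophil-like cells.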

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

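Ranking Scrublet scores, the phagocyte shares of 0.1% and 0.4% in the barcode screen, the total without fibroblast-marker cells, matching on stress, leaving out neutrophil-like cells with phagocyte genes and leaving out the top cell of a gene were chosen only after the results were seen; the other alternatives were planned. No paired analysis was possible because each group is 1 library and no test was made. Of 1586 gene values under alternatives, 1290 stayed within counting error of the reported log2 ratio, 286 moved beyond it and 10 reversed. For list medians these were 328, 51 and 10 of 389, for shares 113, 29 and 1 of 143, and for genes per cell 8, 4 and 2 of 14. A value could count as reversed only where the reported interval left out no difference. Sign changes of the dendritic-like, CD8, other CD4 and naive-like shares are therefore not among the reversed. The naive-like log2 ratio, for example, was -0.27 with doublets kept against 0.17, and the other CD4 one 0.07 at 25% mitochondrial UMIs against -0.15. The cause was not tested unless it is given. The T-like share kept a log2 ratio of 0.48 to 0.76 under its 13 alternatives, all phagocyte clusters -0.28 to -0.11 and fibroblast-marker cells 0.39 to 0.57. Medians kept their sign from -0.59 to -0.44 for alternatively activated and from 0.18 to 0.39 for pro-inflammatory genes in phagocyte-like cells, from -0.33 to -0.27 for interferon-stimulated genes in fibroblast-marker cells and from -0.79 to -0.47 for G2 and M phase genes in NK-like cells, each over 9 alternatives. Depth limits the smaller classes: 14 to 43 cells carry the gamma delta and regulatory T shares, and 195 of 421 VEC and 94 of 293 HTH neutrophil-like cells were too shallow to thin. CD4 T-like cells other than regulatory had a value under only 7 alternatives, and naive-like and gamma delta T cells under 11, because elsewhere no cluster took those names in 1 or both libraries. With each library clustered alone, CD4 T-like cells other than regulatory were 61 of 446 VEC and 0 of 596 HTH T-like cells, and gamma delta T cells 0 and 14, the gamma delta counts opposite to their reported direction. At resolution 2 the dendritic-like class, with 98 and 70 cells, was under the minimum of 100 cells per library for gene values, and at 100 UMIs per member 4 medians could not be given.

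The named mononuclear phagocyte-like log2 ratio of shares was -0.34 at resolution 0.5, -0.33 at resolution 2, -0.20 at 10% and -0.22 at 25% mitochondrial UMIs and -0.36 with 4000 variable genes. It was -0.35 with doublets kept, -0.19 at a phagocyte share of 0.1%, -0.19 without state lists among the variable genes, -0.069 with each library clustered alone and -0.17 without fibroblast-marker cells. For all phagocyte clusters it was -0.28 with doublets kept, -0.27 with Scrublet ranked and -0.11 without fibroblast-marker cells. For fibroblast-marker cells it was 0.39 with doublets kept and 0.42 with Scrublet ranked. Dendritic-like shares gave -0.14 at resolution 2, -0.14 at 500 genes, -0.17 with 4000 variable genes, -0.12 at a phagocyte share of 0.4% and -1.79 clustered alone. NK-like shares gave 0.58 at 10% mitochondrial UMIs, 0.57 without state lists and the reverse, -0.41, clustered alone. The CD8 share of T-like cells gave 0.48 at 10% and 0.36 at 25% mitochondrial UMIs, 0.32 with doublets kept, 0.59 without state lists, 0.51 and 0.38 at phagocyte shares of 0.1% and 0.4%, and -1.61 clustered alone.

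In NK-like cells the lower interferon values reversed at 10% mitochondrial UMIs, to 0.14 for Isg15, 0.36 for Irf7, 0.13 for the interferon-stimulated and 0.19 for the STING median. At resolution 2 these were 0.028, 0.47, 0.13 and 0.20. The NK-like class held 159 VEC and 187 HTH cells at the 10% limit and 166 and 187 at resolution 2, against 234 and 228 as reported. The 10% limit left 9090 of 9111 VEC and 7157 of 7173 HTH cells, and resolution 2 removed none. These reversals therefore go with which cells take the NK-like name, not with the mitochondrial limit alone. Matched on stress, the cytotoxic median stood at 0.14. Hspa1a, itself a gene of the stress list, stood at -0.018 and the stress median at -0.038, both by construction of the matching. In T-like cells the G2 and M phase median was 0.43 as a mean of per-cell CPM. With doublets kept, T-like Spp1 stood at -0.040, Klf4 at 0.0048 and the CD4 helper median at 0.041, which was 0.28 matched on stress. The CD8 mevalonate median was -0.0071 with doublets kept and -0.0092 at a phagocyte share of 0.1%. In fibroblast-marker cells the mevalonate median was 0.0036 when scaled by the median of gene ratios, and the stress median -0.0077 after matching.

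In mononuclear phagocyte-like cells the lipid-associated median was -0.15 with mitochondrial, ribosomal and haemoglobin genes out of the total, -0.14 scaled by the median of gene ratios, -0.25 as a mean of per-cell CPM, -0.12 at resolution 2 and -0.26 matched on stress. The mevalonate median was -0.037 as a mean of per-cell CPM and -0.0098 at 10% mitochondrial UMIs. The stress median was 0.45 as a mean of per-cell CPM, 0.44 at a phagocyte share of 0.1% and 0.0081 after matching, the last by construction. The alternatively activated median was -0.59 with doublets kept and the pro-inflammatory median 0.18 matched on stress. In neutrophil-like cells the interferon-stimulated median was -0.013 as a mean of per-cell CPM. The chemokine median there was -0.25 as that mean, -0.29 with doublets kept, -0.26 at resolution 2, -0.21 matched on stress and -0.11 without cells with phagocyte genes, where Hspa1a stood at -1.12. Without its top cell Ngp stood at 0.46 and Ltf at 0.99, because 1 VEC cell held most of their UMIs.

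Without thinning, the ratio of genes per cell, HTH over VEC, was 0.817 in NK-like, 1.16 in T-like, 1.24 in CD8 T-like and 1.04 in phagocyte-like cells. It reversed to 1.03 in fibroblast-marker and 1.02 in neutrophil-like cells. Unthinned values follow the depth of the cells by construction.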

Other observations

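The 2 tests of matching on stress were set before their results were seen, and the tests of cluster mix, cell pairing, free RNA, Ptprc and Xist were chosen only after the results were seen.

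Ifnb1, which encodes interferon beta, stood at 2.03 CPM (67 UMIs) in VEC and 6.15 CPM (144 UMIs) in HTH mononuclear phagocyte-like cells, a log2 ratio of 1.60 (1.17 to 2.04), while the median of interferon-stimulated genes there was 0.00. How the Ifnb1 UMIs spread over cells, and the ratio matched on stress, were not examined, so this interval may be too narrow. Ifnb1 was picked out after its values were seen, as were the following genes. In dendritic-like cells, the death receptor gene Fas stood at 25.4 CPM in VEC and 12.2 CPM in HTH, with 67 and 29 UMIs, and the metallothionein gene Mt2, which binds metals, at 119 and 55.4 CPM (log2 ratio -1.10, -1.41 to -0.80). In mononuclear phagocyte-like cells Mt2 stood at 394 and 420 CPM. In NK-like cells the phagocyte genes Ccl8, Wfdc17 and Mmp13 stood at log2 ratios of -2.63, -2.28 and -2.22, and Ccl8 at 1003 CPM in VEC, with a UMI in 27.4% of VEC and 8.77% of HTH cells. A single cell held 36.0% of these Ccl8 UMIs in VEC and 68.9% in HTH, and without the top cell of each library the log2 ratio was -3.66.

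In HTH phagocyte-like cells the pro-inflammatory median was above 0 and the alternatively activated median below 0, while the median of stress genes, which digestion of tissue can induce, was above 0 in all 6 classes and these genes took a median of 0.724% of phagocyte UMIs in VEC and 0.920% in HTH. Matched on stress, the alternatively activated median was -0.54 (-0.66 to -0.43, counting error only), with Retnla at -4.23 and Ccl8 at -1.86, and at the VEC mix of clusters it was -0.29 (-0.41 to -0.25), which argues against either as the whole cause, though the second interval only just cleared its bound of -0.25. The pro-inflammatory median, without the 1 gene shared with the stress list, went from 0.31 to 0.158 (0.115 to 0.219) when matched, with Tnf at 0.50 and Ptgs2 at 0.71. Dissociation stress and a response of the cells therefore cannot be told apart for these genes, since inflammatory signals may also induce stress genes and matching removes both, and a part from the mix of clusters stays open too, since the median at the VEC mix was 0.19. The difference between the groups that the study named stays open and untested, because each group is 1 library.

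Barcodes with both lymphoid and phagocyte genes were 872 of the 10190 VEC and 1098 of the 8433 HTH barcodes that passed the filters, 1.37 and 1.43 for each lymphoid barcode without phagocyte genes. Pairing of cells at random, scaled from phagocyte and mesenchymal pairs, would give 169 VEC and 77.3 HTH barcodes, and the numbers seen were 5.15 and 14.2 times as large. Those pairs fell from 147 VEC barcodes (1.44%) to 67 HTH barcodes (0.794%). Barcodes with mesenchymal genes alone rose from 10.1% to 14.4%, and those with phagocyte genes alone fell from 62.6% to 53.1%. Pairing at random alone would not give such a fall, so the number expected in HTH may be too low. Free phagocyte RNA would leave the depth of a lymphoid barcode as it was, but mixed barcodes held 1.90 (VEC) and 1.97 (HTH) times the median UMIs of lymphoid ones. As far as that scale holds, the VEC number argues against random pairing as the whole cause, and the size of the HTH excess is uncertain. The depth argues against free RNA as the whole cause and would go with barcodes of 2 cells. A candidate explanation is lymphoid cells attached to phagocytes, in the tumour or through incomplete dissociation, and attachment, engulfment and an effect of the treatment were not tested.

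Fibroblast-marker cells were 1093 of 9111 VEC and 1263 of 7173 HTH cells, although the series text states a purity above 95% for the CD45 selection, and their median depth was 22493 and 25158 UMIs against 5501.5 and 5982 in phagocyte-like cells. Ptprc, which encodes CD45, stood at 1.48% (VEC) and 0.746% (HTH) of its phagocyte level per UMI, but the screen had removed barcodes with immune genes, and over all 1219 VEC and 1347 HTH barcodes with matrix genes it stood at 5.27% and 3.83%, which leaves an immune cell in the same droplet open, since VEC missed the bound of 5%. Xist, the RNA of the inactive X chromosome, stood at 166 and 196 CPM in phagocyte-like cells, but in the higher of the 2 fibroblast-marker clusters at only 1.67% (VEC) and 2.09% (HTH) of that level, and Ddx3y, a Y-linked gene, had 0 UMIs, which allows up to 0.116 and 0.0919 CPM. The Xist values are consistent with cells of another origin than the immune cells, such as tumour cells, as a hypothesis, and cells of the host that lost Xist stay open. Whether the higher share in HTH comes from the selection or from the tumours was not tested.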
